A study of Mus musculus with 8 samples.

How the data were processed

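The series measured poly(A)-selected RNA of TCMK-1 cells with 8 libraries, 4 of cells with a control shRNA and 4 of cells with an smgGDS shRNA. The labels give 20 µM cisplatin for both groups; a general protocol also mentions saline, but no library is labelled so and none was analysed here. Libraries were made with oligo(dT) beads and the NEBNext Ultra RNA kit, per the labels' protocols. The labels do not say that the 4 libraries of a group came from separate cultures or clones, so each group may be a single line. The p-values therefore measure the spread between these samples, which may be technical.

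The deposited table holds expected counts per gene, which need not be whole, per the file headers and the values, and the authors' FPKM for the same libraries. Fastp 0.18.0, Bowtie2 2.2.8, HISAT2 2.4, StringTie 1.3.1, RSEM, DESeq2 and edgeR are named with no role or order, per the submitters' processing notes, with build GRCm38.p6. The annotation release and strand setting are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. Of the values, 6.52% were not whole (tolerance 1e-09), in 2218 genes of 21879, 1759 of them tested. About 14.2% of the counts of a control library fell in such genes, where reads may be split between near-identical copies or overlapping genes, and they are named as less certain. Coordinates came from a RefSeq gene table of the same build, matched on NCBI gene identifiers for 21728 genes.

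Expected counts as deposited were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. TMM factors, the default expression filter, the robust quasi-likelihood fit and a two-sided F-test on group without covariates were used, with Benjamini-Hochberg adjustment over 11576 tested genes and a threshold of 0.05. Standard errors were derived from the fold change and the F statistic, and intervals cover 95%. The filter removes genes with few counts; 3 counts correspond to 0.187 to 0.259 CPM per library, and such floors cover counting error only. The intervals rest on the spread between libraries. Replicates of a group were compared for duplicates and differed by more than sampling noise, with chi-square per degree of freedom of 1.94 to 3.94. The biological coefficient of variation was 4.29%.

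The 21 gene lists, the test, the alternatives and the rule for named genes were fixed before the data were examined. The text names Rap1gds1, Eif2ak3, Atf4, Ddit3 and Hspa5, the 5 largest rises and 5 largest falls among called genes with at least 5 CPM in the higher group, separated groups and an established symbol, and per list up to 2 members with the smallest adjusted p. Some genes meeting this rule are not reported here. Other list members named as examples were chosen after their values were seen. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over 20 lists. Camera with an estimated correlation called 0 of them, with 2 at an unadjusted p under 0.05. Fry, which asks whether a list's genes move one way on balance and does not compare them with other genes, called the same 6 lists as camera plus the small GTPase (adjusted p = 0.0221) and endothelial (adjusted p = 0.0365) lists. Of the interferon list 2 members, and of the mitochondrially encoded list all 13, had no match in the table under the symbols used.

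Alternatives were other size factors, DESeq2 1.42.0, limma voom, other filters, a replicate term, each library left out, and a threshold of 0.01. Added after seeing the data were a correction for transcript length and GC content (from the longest GENCODE M21 transcript, 11474 tested genes), genes with whole counts only, limma on log2(FPKM + 0.5), and scaling by library total. The procedure was tested on simulated data for the knockdown and control comparison. Counts were drawn for the 11576 tested genes, and the 11476 that passed the expression filter again were scored. Changed genes removed by that filter are not counted. The procedure recovered 19 of 49 genes changed by 0.3 on the log2 scale, 41 of 50 changed by 0.6, 45 of 48 changed by 1 and 49 of 49 changed by 2, with 11 calls among 11280 unchanged genes.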

Results

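Messenger RNA was measured by poly(A)-selected RNA sequencing in TCMK-1 cells, a transformed mouse kidney tubular epithelial line, carrying either an shRNA against smgGDS or a control shRNA. smgGDS, the product of Rap1gds1, binds several small GTPases and promotes their guanine nucleotide exchange and membrane trafficking. Cells of both groups received 20 µM cisplatin, a platinum drug that crosslinks DNA and injures the kidney tubule. The groups held 4 control and 4 knockdown libraries, and libraries without cisplatin were not analysed here, so the comparison concerns the knockdown in treated cells and not the effect of the drug. Total expected counts per library lay between 11560977 and 16059158 in the controls and between 12746051 and 14280962 in the knockdown. Correlations of log2 CPM were 0.991 to 0.994 within groups and 0.986 to 0.992 between them. On the principal component carrying 24.2% of the variance the controls lay between -7.02 and -3.96. Knockdown replicate 4 stood apart at 12.1, against 2.65 to 5.59 in the other knockdown libraries. Gene counts without that library are given beside the gene groups.

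Rap1gds1 fell to 16.2% of its control level in the knockdown (95% interval 13.6% to 19.5%), the smallest p-value among the 11576 genes tested. The gene (ncbi_229877) spans 138925897 to 139075228 on chromosome 3 of GRCm38.p6. It had 276, 258, 241 and 181 counts in control replicates 1 to 4 and 38, 30, 33 and 35 in knockdown replicates 1 to 4. Normalised values were 16.2 ± 0.80 CPM in controls and 2.63 ± 0.19 CPM in the knockdown (SD, n = 4 each). The log2 fold change, given throughout as knockdown minus control, was -2.62 (SE 0.13, edgeR quasi-likelihood adjusted p = 2.72e-19). The authors' FPKM values were 4.73 ± 0.155 and 0.762 ± 0.0359 (SD, n = 4 each), so every library matched its label.

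The comparison asked which transcripts differ when smgGDS is depleted in cisplatin-treated tubular cells, with PERK-dependent endoplasmic reticulum stress named in the study's title. Of the 11576 genes, 1285 rose and 1059 fell in the knockdown, mostly by small amounts. The median absolute log2 fold change of these 2344 genes was 0.24, and 27 of them changed at least 2-fold, 8 upward and 19 downward. That count was 4 with DESeq2, 3 on FPKM, 1 among genes with a mean CPM of at least 5, 59 with no low-count filter and 45 without knockdown replicate 2. The largest rises among genes with at least 5 CPM in the higher group included Ptx3, a secreted pentraxin of innate immunity (log2 fold change 0.86, SE 0.13), the phosphodiesterase Smpdl3a (0.79, SE 0.15), the ubiquitin ligase subunit Dcaf6 (0.77, SE 0.17) and the interferon-induced Ifit2 (0.76, SE 0.10). Dcaf6 and Smpdl3a were low, at 3.83 and 4.22 CPM in controls and 6.42 and 7.31 CPM in the knockdown, while Ifit2 was at 71.9 and 121 CPM. After Rap1gds1 the largest falls were in Pgm2, a phosphoglucomutase (-1.34, SE 0.17), and the transcription factor Tbx2 (-1.10, SE 0.18). Tbl1x, a component of nuclear receptor corepressor complexes, fell by 0.94 on the log2 scale (SE 0.18), and Nfyc, a subunit of the CCAAT-binding factor NF-Y, fell by 0.89 on the log2 scale (SE 0.10). Pgm2, Tbx2 and Tbl1x were also low, at 6.84, 5.17 and 5.36 CPM in controls and 2.69, 2.41 and 2.81 CPM in the knockdown. Adjusted p from edgeR for these 8 rising and falling genes lay between 1.02e-08 for Nfyc and 0.0015 for Ifit2. They were picked from genes with all 4 libraries of one group above all 4 of the other, so that separation adds no support. The shRNA sequence is not given in the sources used here, so off-target silencing of the genes that fell was not tested.

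Among the 2344 called genes, 1852 had groups that did not overlap. Over all tested genes 21.1% had such separation, against 2.86% from chance orderings. Without knockdown replicate 4, 1835 genes passed, of which 1734 were among the 2344. The balance of rises and falls depended on the scaling. Counts scaled by library total alone gave 766 genes higher and 1951 lower, and the authors' FPKM gave 592 higher and 1481 lower. The median log2 fold change of all genes was then -0.06 and -0.05, against 0.00 with TMM factors.

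**Figure D1:**
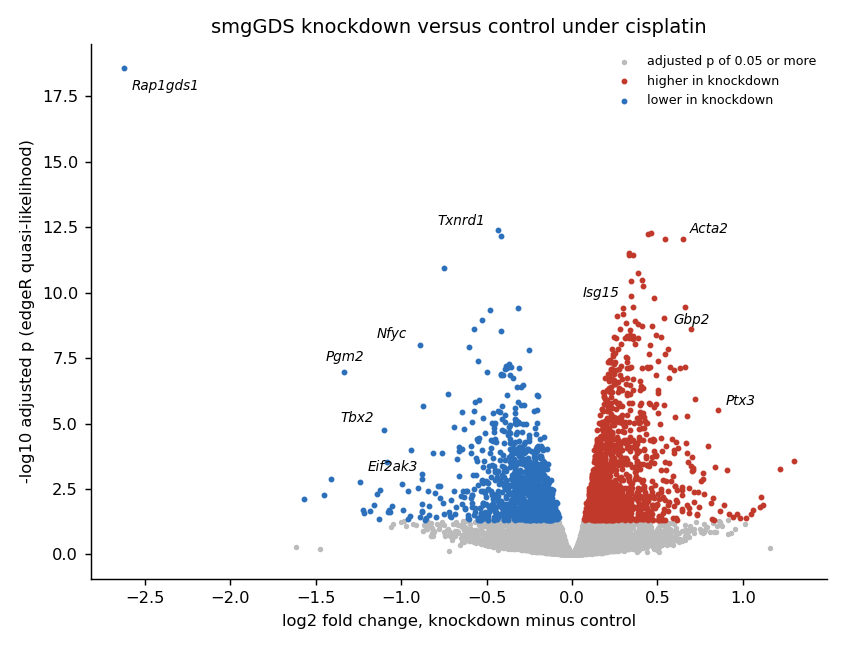
Each point is 1 of 11576 genes, with the log2 fold change (knockdown minus control) on the x axis and -log10 of the edgeR adjusted p on the y axis. Genes passing an adjusted p of 0.05 are red where higher (1285) and blue where lower (1059). Rap1gds1 lies apart at -2.62.

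Eif2ak3, which encodes the endoplasmic reticulum stress kinase PERK, fell to 54.4% of control, while transcripts of many ATF4-driven genes rose slightly. Eif2ak3 was low, at 4.37 ± 0.66 CPM in controls and 2.37 ± 0.76 CPM in the knockdown (SD, n = 4 each, log2 fold change -0.88, SE 0.20, edgeR adjusted p = 0.00128). Ddit3, encoding the stress-induced transcription factor CHOP, rose by 0.18 (SE 0.03, edgeR adjusted p = 6.4e-05), from 270 ± 10.6 to 306 ± 8.58 CPM. Atf4 mRNA was 570 ± 11.1 and 587 ± 4.45 CPM and did not pass (log2 fold change 0.04, SE 0.03, edgeR adjusted p = 0.302). Its estimate was -0.01 under total-count scaling and 0.08, past the threshold, after correction for transcript length and GC content. Hspa5, the chaperone BiP, was 1755 ± 25.3 and 1696 ± 47.3 CPM (log2 fold change -0.05, SE 0.03, edgeR adjusted p = 0.189). Under total-count scaling and on FPKM its estimate was -0.11 and passed.

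**Figure D2:**
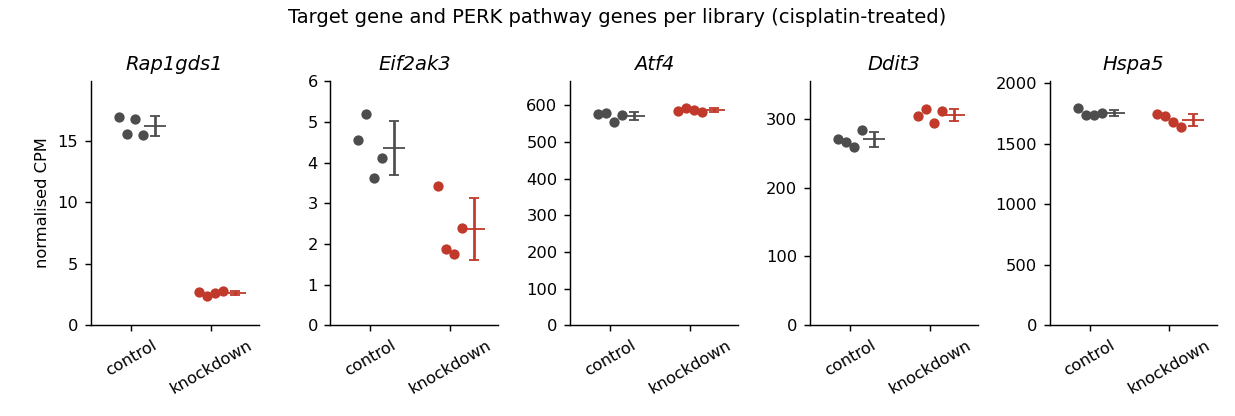
Normalised CPM of Rap1gds1, Eif2ak3, Atf4, Ddit3 and Hspa5 in each library, with the 4 control libraries in grey and the 4 knockdown libraries in red. Horizontal bars are group means and vertical bars are SD. Rap1gds1 and Eif2ak3 were lower, and Ddit3 and Atf4 higher, in all 4 knockdown libraries than in any control, although Atf4 did not pass the test and its estimate was -0.01 under total-count scaling.

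Of the 27 PERK-ATF4 integrated stress response genes, 15 rose and 3 fell. The risers included the asparaginyl-tRNA synthetase Nars (0.21, SE 0.03), the amino acid transporter subunit Slc3a2 (0.19, SE 0.03) and the pseudokinase Trib3 (0.22, SE 0.04). The 3 that fell were Eif2ak3 itself and Ddit4 (-0.20) and Sesn2 (-0.40), both inhibitors of mTORC1 signalling. Adjusted over the list alone, 16 rose and 3 fell. The list's median log2 fold change was 0.11 and camera called it upward (adjusted p = 0.000207). With an estimated correlation it was not called (adjusted p = 0.0797 with an estimated correlation). Without knockdown replicate 4, 13 rose and 3 fell. Under total-count scaling 10 rose and 3 fell with a median of 0.06, and on FPKM 9 rose and 3 fell with a median of 0.05. Slc3a2 has counts that are not whole and is less certain.

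Chaperones and other ATF6 or XBP1 targets did not move as a group. Of 23 tested, 4 rose, among them the stress sensor Atf6 (0.37, SE 0.09), the secreted factor Manf (0.13, SE 0.03) and the transcription factor Xbp1 (0.23, SE 0.06), and 3 fell, including the chaperone Hsp90b1 (-0.09, SE 0.03). Counts were the same adjusted over the list alone and without knockdown replicate 4. Without control replicate 1, 4 rose and 1 fell, and under total-count scaling 3 rose and 7 fell. The median was 0.00 (camera adjusted p = 0.714) and became -0.05 under total-count scaling and on FPKM. Manf lost its call under both of these scalings, and Atf6 lost its call on FPKM.

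Targets of p53 fell, with 10 of 24 lower and 1 higher. Cdkn1a, encoding the cell cycle inhibitor p21, went from 736 ± 16.2 to 619 ± 22.9 CPM (SD, n = 4 each, log2 fold change -0.25, SE 0.03, edgeR adjusted p = 1.61e-08). The death receptor Tnfrsf10b fell by 0.39 on the log2 scale (SE 0.05), Zmat3 fell by 0.56 and Sesn1 fell by 0.88. Gdf15, a stress-induced cytokine that ATF4 also drives, was the 1 member that rose (0.24). Adjusted over the list alone the counts were the same. The median was -0.24 and camera called the list downward (adjusted p = 0.000382), but not with an estimated correlation (adjusted p = 0.484 with an estimated correlation). Without knockdown replicate 4, 1 rose and 8 fell. Gdf15 was not called without knockdown replicate 3. Counts of Tnfrsf10b are not all whole, so it is less certain.

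G2/M cell cycle genes fell together, 17 of 25, and none rose. The mitotic kinase Aurka fell by 0.21 (SE 0.04) and the proliferation marker Mki67 fell by 0.19 (SE 0.03) on the log2 scale, with Hmmr at -0.41 and Ccnb1 at -0.28. Adjusted over the list alone the count was again 17. The median was -0.19 (camera adjusted p = 1.94e-06), with no call once the correlation was estimated (adjusted p = 0.484 with an estimated correlation). Without knockdown replicate 4, 14 fell. Of 25 S phase and DNA replication genes, 4 fell, both by the all-gene adjustment and adjusted over the list alone, among them the flap endonuclease Fen1 (-0.12, SE 0.03) and cyclin Ccne2 (-0.24, SE 0.07), with a camera adjusted p of 0.714. This count was 1 without control replicate 2, 2 without knockdown replicate 3, 1 without knockdown replicate 4 and 7 under total-count scaling. Fen1 lost its call without knockdown replicate 4 and after the length and GC correction. Ccne2, which has counts that are not whole, lost its call without control replicate 2, knockdown replicate 3 or knockdown replicate 4. DNA crosslink and double-strand break repair genes showed 1 rise and 1 fall in 23, also when adjusted over the list alone and without knockdown replicate 4. These were the checkpoint kinase Atr (0.33, SE 0.10) and the damage sensor Xpc (-0.24, SE 0.07), with a camera adjusted p of 0.714 for the list. Atr was not called without control replicate 1, control replicate 2 or knockdown replicate 3, on FPKM or after the length and GC correction, and 4 list members fell under total-count scaling. Without control replicate 3, 2 repair genes rose and 2 fell.

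Interferon-stimulated genes rose together, with 22 of 26 higher and none lower, including when adjusted over the list alone and without knockdown replicate 4. Isg15, a ubiquitin-like modifier, rose from 640 ± 12.6 to 786 ± 31.3 CPM (SD, n = 4 each, log2 fold change 0.30, SE 0.03, edgeR adjusted p = 3.85e-10). The guanylate-binding protein Gbp2 rose by 0.54 (SE 0.05) and the cytosolic RNA sensor Ifih1 rose by 0.38. The list median was 0.28 (camera adjusted p = 4.05e-13), and the call was lost when the correlation was estimated (adjusted p = 0.343 with an estimated correlation). In total 18 members rose under total-count scaling. Among 15 NF-kB and inflammatory mediators 3 rose and none fell, by both the all-gene adjustment and adjusted over the list alone, led by Cxcl10 (0.55, SE 0.13), a chemokine that interferon also induces, and the growth factor Csf1 (0.16, SE 0.04). Only 1 rose without knockdown replicate 4, where Csf1 lost its call, as it did under total-count scaling and on FPKM. Under total-count scaling 1 rose and 2 fell. With TMM factors the median was -0.07 while the mean was 0.02 (camera adjusted p = 0.773).

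Actin cytoskeleton and SRF/YAP target genes rose, 14 of 20, with none lower. Acta2, encoding smooth muscle actin, went from 430 ± 25.6 to 673 ± 31.3 CPM (SD, n = 4 each, log2 fold change 0.65, SE 0.04, edgeR adjusted p = 8.59e-13). The actin-binding calponin Cnn2 rose by 0.34 (SE 0.04), vinculin (Vcl) rose by 0.44 and the alpha-actinin gene Actn1 rose by 0.42. Adjusted over the list alone 14 rose and 1 fell, as they did without knockdown replicate 4. The median was 0.25 (camera adjusted p = 4.62e-08), without a call when the correlation was estimated (adjusted p = 0.343 with an estimated correlation). Extracellular matrix and mesenchymal genes rose as well, with 13 of 22 higher and 1 lower, by both adjustments (adjusted over the list alone the counts were the same) and without knockdown replicate 4. The collagen crosslinking enzyme Lox rose by 0.25 (SE 0.03), and the basement membrane collagens Col4a1 and Col4a2 rose by 0.55 and 0.59. The metalloproteinase inhibitor Timp1 was the 1 that fell (-0.14). Of 4 tested fibroblast and pericyte markers 2 also rose, Dcn (0.49) and Pdgfrb (0.36). The matrix list's median was 0.21 (camera adjusted p = 0.000111), and its call was not kept with an estimated correlation (adjusted p = 0.484 with an estimated correlation).

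**Figure D3:**
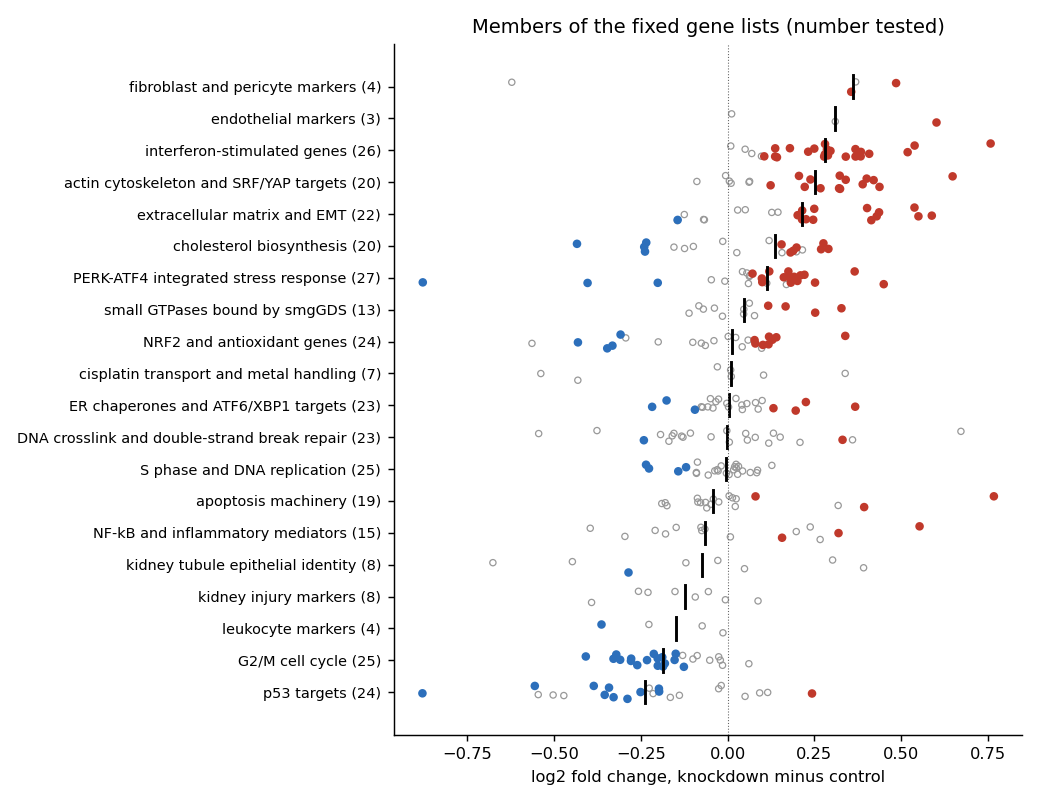
Log2 fold change (knockdown minus control, x axis) of each tested member of 20 fixed gene lists (y axis, number tested in brackets). Filled points passed an edgeR adjusted p of 0.05, red for higher and blue for lower, open points did not, and black ticks are list medians. The interferon list holds 22 filled red points and the G2/M list 17 filled blue points. With total-count scaling the medians of the small GTPase, NRF2, cisplatin transport and chaperone lists move below 0.

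Genes of the NRF2 antioxidant response moved in both directions, 8 up and 4 down of 24. The falls included Txnrd1 (thioredoxin reductase, -0.43, SE 0.03, edgeR adjusted p = 4.10e-13), Hmox1 (haem oxygenase, -0.33, SE 0.05), Nqo1 (-0.31) and Osgin1 (-0.35). The rises included Me1 (0.34) and Prdx1 (0.12). Adjusted over the list alone 8 rose and 5 fell. The median was 0.01, the mean -0.06 and camera pointed downward (adjusted p = 0.773), and under total-count scaling the median was -0.04. The number of rises fell to 3 without control replicate 1 or 2, to 5 without knockdown replicate 1, to 4 without knockdown replicate 3 or 4, and to 1 under total-count scaling or on FPKM, while 4 fell in each of these leave-out fits and 7 under total-count scaling. Cholesterol synthesis genes were likewise split, 7 up and 4 down of 20, also when adjusted over the list alone. The isomerase Idi1 (0.27, SE 0.05, counts not all whole) and lanosterol synthase Lss (0.29, SE 0.06) rose, and the reductase Dhcr7 (-0.43) fell (median 0.14, camera adjusted p = 0.414). Without knockdown replicate 4, 5 rose and 4 fell. Total-count scaling gave 3 rises and FPKM gave 1, where Lss lost its call.

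Small GTPases known to bind smgGDS showed 4 rises and no fall among 13. These were Rhoc (0.17, SE 0.03), Rap1a (0.33, SE 0.08), Rala (0.25, SE 0.08) and Cdc42 (0.12, SE 0.04), and adjusted over the list alone 4 rose and 1 fell. The median was 0.05 (camera adjusted p = 0.378) and turned to -0.01 under total-count scaling. Only 2 rose without control replicate 2, knockdown replicate 1 or knockdown replicate 4, with DESeq2, on FPKM and under total-count scaling. In the apoptosis list, 3 of 19 rose and none fell, also when adjusted over the list alone. Casp12, an endoplasmic reticulum caspase, rose by 0.77 (SE 0.18), from 2.80 ± 0.469 to 4.80 ± 0.303 CPM. The apoptosis median was -0.04 and the mean 0.03 (camera adjusted p = 0.969), 2 members rose without knockdown replicate 4, 3 rose and 2 fell without knockdown replicate 2, and under total-count scaling 2 rose and 4 fell.

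Few kidney genes passed the test, and others had too few counts to be tested. Of 18 tubule identity genes 8 were tested, of 10 injury markers 8, and of 11 cisplatin transport and metal handling genes 7. Those left out included the tubule regulator Hnf4a, the injury marker Havcr1 and the transporter Slc22a2, each with a highest count of 0 in any library. The water channel Aqp1 fell by 0.29 on the log2 scale (SE 0.04), from 155 ± 6.07 to 127 ± 3.63 CPM, the 1 call among 8 tested tubule identity genes (camera adjusted p = 0.414). Among 8 kidney injury markers edgeR, DESeq2 and voom each called 0, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.405). By edgeR 1 fell without knockdown replicate 3 and 1 fell under total-count scaling. Among 7 cisplatin transport and metal handling genes each called 0, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.914). The transport list's median of 0.01 was -0.05 under total-count scaling, and its mean was -0.08. Of the other cell types' markers few were measurable. The leukocyte list had 1 fall in 4 (Cd14, -0.36, SE 0.06, camera adjusted p = 0.321) and the endothelial list 1 rise in 3 (Flt1, 0.60, SE 0.11, camera adjusted p = 0.293). The fibroblast and pericyte list had 2 rises in 4, the proteoglycan Dcn (0.49, SE 0.15) and the receptor Pdgfrb (0.36, SE 0.11), with a camera adjusted p of 0.321. Counts adjusted over the list alone were the same for all 6 lists. Without knockdown replicate 4, Dcn lost its call and 1 fibroblast marker rose, with the other lists unchanged in their counts. Dcn also lost its call without control replicate 2, and Pdgfrb lost its call without control replicate 3 or knockdown replicate 3 and on FPKM. Genes encoded by mitochondrial DNA were not analysed here.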

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

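The tests of other splits were planned; no test in this part was chosen after its result was seen. Of 102 groups of 4 libraries examined, 5 held a library far from the other 3. Chance gives about 1 in 20 for independent groups, but these share the same 8 libraries, so the rate decides nothing. Knockdown replicate 4, which also stood apart on the principal component, was the high library for Cnn2, Flt1 and Dcn. Cnn2 was 350 CPM in knockdown replicate 4 against 315 to 318 in the other knockdown libraries (gap over range 0.917). Flt1 was 13.3 CPM in knockdown replicate 4 against 11.5 to 11.8 (0.866). Dcn was 6.79 CPM in that library against 5.78 to 5.85 (0.932). Fen1 was 536 CPM in control replicate 1 against 561 to 564 in the other controls (0.873). Total counts were 14280962 in knockdown replicate 1 against 12746051 to 12902835 in the other knockdown libraries (0.898).

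Over all 35 splits of the 8 libraries into 4 and 4, the real one gave 2344 called genes and any other at most 1. The real split thus stood alone (1 of 35 splits), the smallest share that 35 splits can give. Every other split mixes libraries of both groups, so a difference between the groups itself lowers its count. The splits argue against an arbitrary labelling of these 8 libraries. They cannot tell smgGDS depletion from other differences between the groups. Genes changed at least 2-fold numbered 27 in the real split and at most 1 in the others (1 of 35 splits). They are part of the called genes, so this count is no separate test. For the number of called lists an arbitrary labelling cannot be set aside. In 8 of 35 splits, the real one included, at least the 6 lists of the real split were called, with 7 the highest of the others. The other 7 such splits all exchanged a single library between the groups and so kept 3 of 4 libraries of each group together, whereas the 18 splits into 2 and 2 gave at most 2 lists.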

How the results depend on the processing

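Tests on length and GC content, whole counts, FPKM and total-count scaling were chosen after the data were seen. Rap1gds1 passed in the same direction under all alternatives run. The count of 2344 changed genes ranged from 1835 (without knockdown replicate 4) to 2717 (total-count scaling) at the threshold of 0.05, with 1957 by DESeq2, of which 1935 were among the 2344; at a threshold of 0.01 it was 1405, and 13 for 2-fold changes. The count of 27 genes changed at least 2-fold was 4 with DESeq2, 59 with no low-count filter, 1 with a mean CPM of at least 5 (Rap1gds1), and 3 with limma on FPKM. Leaving out 1 library gave 29 to 45, the highest without knockdown replicate 2. The filters add or remove low genes by construction; for the others the cause was not tested. Of 20 tested lists camera called 6 and, with an estimated correlation, 0 (2 at an unadjusted p under 0.05), while fry called 8. Of 46 named genes other than Rap1gds1, 35 kept direction and call in every setting that tested them (19 settings for 36 of the 46 and 18 for the others), 11 changed call in at least 1 and 0 reversed a called direction. Replicate numbers were not treated as pairs: same-number correlations were -0.0365 to 0.0828 and others -0.062 to 0.0377, and 3 of 4 knockdown libraries matched their own number best, a hint of weak pairing from the data alone. A replicate block gave 2660 changed genes, 28 at least 2-fold and 6 lists. At these depths and with 4 libraries per group, 38.8% of simulated changes of 0.3 on the log2 scale were recovered. In that simulation 11280 of 11476 genes were unchanged, whereas 2344 of 11576 were called in the data. The adjustment is stricter with fewer changed genes, so the simulated recovery may not carry over to the data. Which of depth, sample number, spread and share of changed genes sets that limit was not tested.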

Other observations

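The tests of annotated pathways and transcription factors, the choice of the lists and of the span trend to weigh, and the test on Trp53 came after the results were seen. Ribosomal protein genes rose widely, 67 of 130 in the authors' KEGG annotation with 2 lower (median log2 fold change 0.11, camera adjusted p = 7.28e-08, adjusted p = 0.409 with an estimated correlation). Rpl5 rose from 1595 to 1862 CPM and Rps24 from 2134 to 2473 CPM, and 27 of the 130 genes have counts that are not whole. In this group 60 rose and 1 fell without knockdown replicate 4, 43 rose and 5 fell under total-count scaling, and 39 rose and 4 fell on FPKM, with a median of 0.05 under each of these scalings. Focal adhesion genes rose as well, 51 of 157 with 5 lower (median 0.12, camera adjusted p = 0.000204, adjusted p = 0.396 with an estimated correlation), including talin (Tln1, 0.36), integrin-linked kinase (Ilk, 0.39) and caveolin (Cav1, 0.32). Here 41 rose and 4 fell without knockdown replicate 4, 37 rose and 12 fell under total-count scaling (median 0.06), and 30 rose and 6 fell on FPKM (median 0.05). In all, 25 of 288 pathways were called upward and 0 downward by camera, with 0 downward at an unadjusted p under 0.05. With an estimated correlation 0 were called and 27 had an unadjusted p under 0.05. The annotated p53 signaling pathway was not called, with 10 rises and 19 falls among 64 genes (median -0.09, camera adjusted p = 0.184). Nor was the annotated cell cycle pathway, with 14 rises and 22 falls among 118 genes (median -0.02, camera adjusted p = 0.531). Both hold more genes than the fixed p53 and G2/M lists.

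Transcription factor genes tended to be lower. Of 899 in the authors' annotation 126 fell and 45 rose (median -0.08, camera p = 0.000248, and p = 0.00221 with an estimated correlation). Falls included the homeobox gene Hoxc13 (-0.60) and the zinc finger gene Zfp385a (-0.48), and rises included Mef2a (0.66) and the interferon regulatory factor Irf5 (0.66). Of these genes 104 fell and 34 rose without knockdown replicate 4, under total-count scaling 205 fell and 26 rose (median -0.14), and on FPKM 152 fell and 15 rose (median -0.11). Counts of 178 of the 899 are not all whole.

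Prompted by names among the largest changes, log2 fold change was set against the genomic span of 11465 genes, which are not independent replicates. Long genes were higher in the knockdown, with a Spearman rho of 0.23 (interval 0.212 to 0.248). In the tenth with the longest span (median 156 kb) the median was 0.18, with 19.1% risen and 1.31% fallen, against -0.03 in the shortest (2.87 kb); these medians were 0.12 and -0.08 under total-count scaling and 0.06 and -0.07 on FPKM. Bias with transcript length and GC content is argued against as the whole cause by a rho of 0.151 after its removal, and a single deviating library by a rho of at least 0.192 without any 1 library; each knockdown library gave at least 0.121 against the control mean, which they share, where each control against the other controls gave -0.0183 to 0.0471. Cisplatin lesions block polymerases along transcribed DNA, so fewer of them may leave long genes higher, and the partial rho given transcript length was 0.234, but without untreated libraries this cannot be told apart from an effect of the knockdown that needs no cisplatin.

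The falls of the p53 and G2/M lists and the rises of the interferon, actin and matrix lists were weighed together. Length and GC bias is argued against as the whole cause, since each list kept at least 85.4% of its median and its camera call at the preset correlation after the correction; without the correction, adjusted p was 0.343 or 0.484 for these lists with an estimated correlation. No single library carried them, since at least 71.7% of each median was kept without any 1 of the 8 libraries, the lowest being the p53 list without control replicate 2. An effect of the knockdown on these programmes remains a hypothesis, since the labels do not say that a group held more than 1 line. Effects of the shRNA other than smgGDS depletion were not tested either, for the rising lists as for the falling ones.

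The p53 list could fall through less Trp53 mRNA. Trp53 had a log2 fold change of -0.04 (edgeR adjusted p = 0.364), and its interval from -0.11 to 0.02 lies above the list median of -0.24. A fall of Trp53 mRNA as large as that of the list is therefore argued against. A smaller fall within the interval is not, and whether it could lower the targets was not tested. The protein p53 was not measured here.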
